A study of Eohaustorius estuarius with 16 samples.

How the data were processed

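Whole-body RNA extracts of 16 samples of Eohaustorius estuarius, 8 solvent controls and 8 exposed to cyfluthrin, were measured on single-colour Agilent arrays in 1 laboratory. Groups and replicate numbers were taken from the labels. The labels describe the samples of a group as separate animals' extracts and say nothing more of how they were collected. Samples of the other laboratories were not analysed here.

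Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1; the submitters' processing notes name version 9.1. Their processed signal, median signal and local background are deposited as spot intensity values on a linear scale, and the processed signal already has the background subtracted, per the file headers. The headers show that both slides were read at different times and with different extraction protocols, GE1_107_Sep09 for slide 1 and GE1-v1_95_Feb07 for slide 2. Slide 1 held 0 processed signals below zero and slide 2 held 1477, or 1.21% of its spots. The authors' deposited value table holds log2 values of 8567 rows, 8507 for probes and 60 for control probes. Set against the scanner values, its columns correlated with quantile-normalized, row-centred log2 signals at a median r of 0.973 (0.941 to 0.989), with a median slope of 1.04. Every row median is 0 within 5e-07, and column medians ranged from -0.04 to 0.05. The scale and the direction follow from this comparison and the centring from the row medians; how the authors normalized is not given in the sources used here.

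From the scanner files, the processed signal of each spot was divided by the array's 75th percentile over non-control spots. Values under 0.02 of that percentile were set to 0.02 before taking log2, and spots of a probe were averaged. The floor of 0.02 was chosen after the files were examined, from the lowest signals still well above background. Control spots, and spots marked as non-uniform or as population outliers, were left out. A probe was tested if well above background on at least 8 of the 16 arrays, whatever their group; 7556 of 8507 probes were, and 951 were not tested. Of all probes, 6039 were detected on all 16 arrays and 86 on none. Folds of probes near the floor are understated. For arrays the number of arrays limits the precision.

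Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Single values per array were compared with exact permutation tests over all 12870 assignments. Principal components were taken of centred log2 values, with missing values (75 probes) filled by the probe's mean. The slide was a batch, so the number of called probes is given with the slide as a block and within each slide; counts of probes whose groups do not overlap are given over all 16 arrays only. The fit was tested on simulated data made from the real means, spreads and slide effects of the 7556 probes, with 200 probes changed per run in 5 runs. For the comparison of exposed with control arrays without a slide block it recovered 24.4% of 1.5-fold, 63.6% of 2-fold, 92.4% of 4-fold and 97.6% of 8-fold changes, and 3.74% of its calls were false; with the slide block 6.16% of the calls were false, above the share of 0.05 set as the threshold. The simulated noise was drawn independently for each probe and array, without the variation that probes of a real array share. The simulated shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.

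The named probes are those with the steepest rise (2) and fall (2) among the probes that passed, since the fixed rule allowed no more where probes have no gene names. The 19 gene lists fixed before the data were examined, tissue markers among them, matched 0 probes, because probe annotations hold contig numbers only; list tests were therefore not run. Groups, main tests, gene lists and most alternatives were fixed before the data were examined. The alternatives were other background correction, scaling, filters, blocks, weights, thresholds, the authors' value table and leaving out single arrays. The normexp alternative used the median signal in place of the mean signal, a column the files do not hold, with an offset of 50.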

Results

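Gene expression was measured in the estuarine amphipod Eohaustorius estuarius, a small burrowing crustacean used in sediment toxicity tests. Animals had spent 10 days in sediment spiked with cyfluthrin, a pyrethroid insecticide that acts on the voltage-gated sodium channels of nerve cells, at a nominal 1.6 µg/kg, or in sediment spiked with solvent alone. RNA extracts of whole bodies, 8 from solvent controls and 8 from exposed animals, were each labelled with Cy3 and hybridised to 1 array in laboratory A of an interlaboratory comparison of microarray data. Each array carried 8507 probes, each designed to a different assembled transcript (contig). The files do not pair the contigs with gene names, so no gene family or pathway can be named, and only the 4 contigs chosen by a fixed rule are given by their identifiers. The 75th percentile of the spot signal ranged from 240 to 381 on the 8 arrays of slide 1 and from 347 to 633 on the 8 arrays of slide 2. Each slide held 4 control and 4 exposed arrays. On both slides the controls lay in row 1 and the exposed animals in row 2, so the row of the slide and the exposure cannot be told apart.

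The first question was which transcripts changed in animals exposed to cyfluthrin. Rises and falls were about equal in number and, at the median, similar in size: 2.02-fold for the probes called higher and 1.85-fold for those called lower. They differed at the extremes, where a small set of probes rose steeply. Of 7556 probes tested, 86 were higher and 87 were lower in exposed animals at an adjusted p below 0.05 (limma, Benjamini-Hochberg; n = 8 per group), which is 2.29% of those tested. Among the called probes, 30 were at least 4-fold higher and 6 at least 4-fold lower, and 22 were at least 8-fold higher against 0 at least 8-fold lower. At an unadjusted p below 0.05 there were 1003 probes, where 378 would be reached by chance. The even split between directions depended on the setting: median scaling called 60 probes higher and 36 lower, no scaling called 44 higher and 11 lower, and slide and background covariates called 193 higher and 332 lower.

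The 30 probes called at least 4-fold higher rose by a median of 9.33-fold. For each of them, all 8 exposed arrays lay above all 8 control arrays. Over all tested probes, 53 had every exposed array above every control array and 37 had every exposed array below, where chance would give 1.17 in both directions together. The 30 probes were not without signal in control animals. Of them, 26 were well above background on all 8 control arrays and none was undetected on every control array. Their median level went from 0.302 of the array's 75th percentile in controls to 2.87 times that percentile in exposed animals. The mean log2 level of the 30 probes was -1.67 ± 0.61 in controls and 1.49 ± 0.49 in exposed animals (SD, n = 8 each), and the highest control, at -0.61, lay below the lowest exposed array, at 0.84. These probes were chosen for their difference, so the gap between the groups describes its size and is no separate test. Their spots lay closer together on the array than in most random sets of probes, with a share of 0.043 of 1000 random sets as close. Spots of other tested probes within 3 positions of them had a median change of -0.079 (log2).

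**Figure D1:**
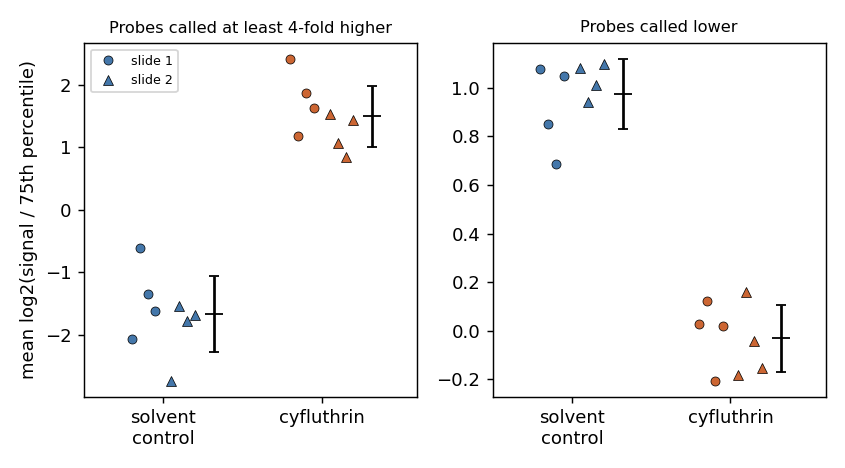
Mean log2 signal, relative to the array's 75th percentile, of the 30 probes called at least 4-fold higher (left) and of the 87 probes called lower (right) on each array, by group; circles are slide 1 and triangles slide 2, and the bar is the mean ± SD of 8 arrays. In both panels the exposed and control arrays do not overlap, and the probes were selected on these same arrays.

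The median level of the 87 probes called lower was 1.66 times the 75th percentile in controls and 0.798 times it in exposed animals. Of these 87, 27 fell at least 2-fold, while 43 of the 86 probes called higher rose at least 2-fold and the other 43 less. The mean log2 level of the 87 probes was 0.97 ± 0.14 in controls and -0.03 ± 0.14 in exposed animals (SD, n = 8 each). For 34 of them every exposed array lay below every control array. No probe was detected on all 8 arrays of one group and on none of the other.

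The probe of contig_7650 showed the steepest rise. Its log2 level went from -2.01 ± 1.06 in controls to 1.73 ± 0.59 in exposed animals (SD, n = 8 each), a rise of 13.3-fold with a 95% confidence interval of 7.40 to 24.0. The log2 change was 3.74 (SE 0.40, limma adjusted p = 2.03e-05). The probe of contig_3691 rose about as far, from -0.92 ± 1.20 to 2.81 ± 0.55 (SD, n = 8 each), with a log2 change of 3.73 (SE 0.44, limma adjusted p = 4.13e-05). For both, all 8 exposed arrays lay above all 8 controls, and for contig_3691 one control array, control 5, stood apart at -3.42.

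The steepest called fall was that of contig_2561, from 1.97 ± 0.53 in controls to -0.41 ± 0.39 in exposed animals on the log2 scale (SD, n = 8 each). Its log2 change was -2.39 (SE 0.23, limma adjusted p = 5.92e-06), and the control level was 5.23 times the exposed one. The contig_807 level went from 2.94 ± 0.98 to 0.64 ± 0.82 (SD, n = 8 each), a log2 change of -2.30 (SE 0.42, limma adjusted p = 0.0044). Its groups overlapped, with control 3 at 0.80 apart from the other controls. The fall of contig_807 was -3.34 on slide 2 (limma adjusted p = 0.0063) and -1.26 on slide 1, where it did not pass (limma adjusted p = 0.287); the slide-by-exposure term had an unadjusted limma p of 0.011 and no probe passed that test after adjustment. Larger fitted falls occurred among probes that did not pass: 12 probes had one, the largest at -4.05 (SE 1.30, limma adjusted p = 0.143).

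**Figure D2:**
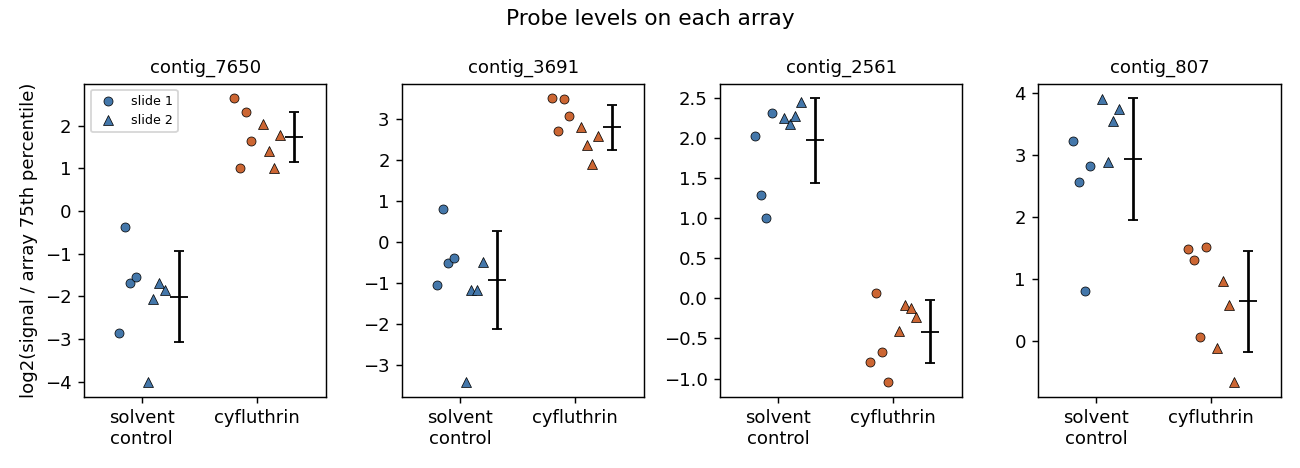
Log2 signal relative to the array's 75th percentile of the 4 named probes on each array, by group; circles are slide 1, triangles slide 2, and the bar is the mean ± SD of 8 arrays. The exposed arrays lie above all controls for contig_7650 and contig_3691 and below all controls for contig_2561, while for contig_807 the groups overlap.

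The 30 steeply raised probes rose on both slides, analysed apart with 4 control and 4 exposed arrays each. Of them, 30 were called on slide 1 and 29 on slide 2. The 30 were chosen over these same arrays, so a rise on each slide was favoured in advance and is no separate test. Over all tested probes, slide 1 gave 95 calls (44 higher, 51 lower) and slide 2 gave 91 (42 higher, 49 lower). Of these, 42 probes were called on both, all in the same direction, 34 higher and 8 lower; independent lists would share 0.245 higher and 0.331 lower. Of the probes called on slide 1, 77 moved the same way on slide 2, and of those called on slide 2, 89 moved the same way on slide 1. Across all tested probes the direction matched in 49.8%. The median change of all tested probes was -0.20 on slide 1 and 0.08 on slide 2 (log2), and with each slide's changes centred on its median the direction matched in 47.4%. The changes on the slides correlated at r = 0.13 (Spearman's rho = -0.04) across probes, which are not independent replicates. With the slide as a block, 290 probes were called, 136 higher and 154 lower, among them all 173 of the calls without it. At least 4-fold, the block called 30 higher and 6 lower, and at least 2-fold 44 higher and 31 lower; at an unadjusted p below 0.05 there were 1336 probes. The difference in exposure effect between the slides passed for 0 probes in limma, with a lowest adjusted p of 0.187. At an unadjusted p below 0.05 there were 816 probes, where 378 would be reached by chance. An exposure effect that differs between the slides is therefore not excluded.

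**Figure D3:**
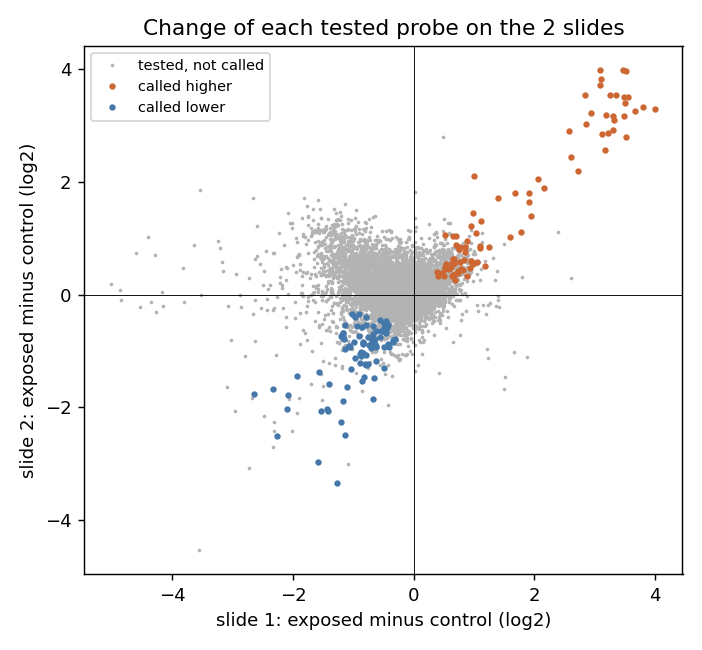
Log2 change (exposed minus control) of each tested probe on slide 1 (horizontal) and slide 2 (vertical), with 4 control and 4 exposed arrays per slide; orange points are the 86 probes called higher over all 16 arrays, blue points the 87 called lower, grey points the others. The called probes lie along the diagonal, a place their selection on the same arrays favours, and the grey cloud shows no such relation (r = 0.13 over all tested probes).

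A further question was how far exposure set the arrays apart against the spread between animals. Arrays of one group resembled each other slightly more than arrays of different groups, a small difference that did not hold in every setting. The median correlation of log2 levels was 0.936 between arrays of one group and 0.929 between arrays of different groups, a difference of 0.0074 (one-sided exact p = 0.039 over the 6435 splits of the arrays into groups of 8). Correlations of levels lie near their ceiling because probes differ so much in signal; on the authors' row-centred values the same difference was 0.131 (one-sided exact p = 0.039). Without the filter on dim probes it was 0.0046 and did not pass (one-sided exact p = 0.12). Matched on slide, it was 0.0034 for pairs of arrays on one slide and 0.0038 for pairs on different slides, and neither passed over the 2450 splits made within slides (one-sided exact p = 0.19 and 0.14). Over all pairs, the difference of 0.0074 did pass over those same splits (one-sided exact p = 0.039). The first principal component held 34.7% of the variance and did not separate the groups (exact permutation p = 0.46, two-sided, n = 8 per group), nor did the second, with 17.6% (exact permutation p = 0.12). The fourth, with 9.7%, differed between the groups by -22.4 (exact permutation p = 0.0081), but did not pass after adjustment over the 8 array measures tested (Benjamini-Hochberg adjusted exact p = 0.065). With arrays permuted only within slides it did pass (exact permutation p = 0.0053, adjusted 0.042), the only one of the 8 measures to do so. The slide set more probes apart than exposure did: 1409 differed between the slides in limma, 918 higher on slide 2 and 491 lower.

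**Figure D4:**
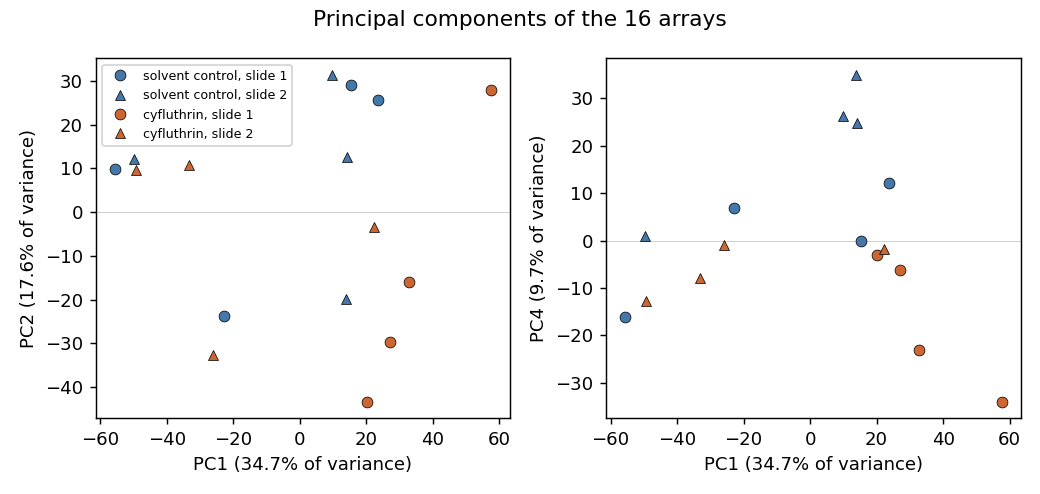
First principal component against the second (left) and the fourth (right) of the log2 levels of the tested probes on the 16 arrays; blue points are solvent controls, orange points exposed animals, circles slide 1 and triangles slide 2. Groups mix along the first component (34.7% of the variance), and exposed arrays lie lower on the fourth (9.7%), with overlap.

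Measures of array quality did not separate exposed from control arrays, although only large differences could be detected with 8 arrays per group. The 75th percentile was 8.50 ± 0.40 in controls and 8.69 ± 0.52 in exposed animals (log2, SD, n = 8 each; exact permutation p = 0.41). The net signal of the negative control spots was 5.15 ± 0.32 and 5.24 ± 0.52 (log2, SD, n = 8 each; exact permutation p = 0.69). The share of probes well above background was 87.3% ± 5.60 and 88.3% ± 6.36 (SD, n = 8 each; exact permutation p = 0.74). Within slides, the difference in that share (exposed minus control) was -3.94 percentage points on slide 1 and 5.93 points on slide 2. No spot was saturated. The spike-in probe E1A_r60_a97 read between 4709 and 7750 on the arrays of slide 2 but between 1.94 and 94.9 on those of slide 1. The median SD between duplicate spots on an array was 0.16 on the log2 scale, against 0.43 between arrays of one group, and the latter was larger for 91.8% of the 5535 tested probes with a pair of spots. The SD between arrays includes the difference between the slides, and duplicate spots share 1 labelling and hybridisation. The gap is therefore not the spread between animals alone.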

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

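The tests of the 30 steep probes' neighbouring spots, and those of the swinging probes for loss of signal, slide and exposure, were chosen only after the results were seen. Among 30 groups of 8 arrays examined for a single array far from the others, 2 had one, where chance gives about 1 in 20 groups, or 1.5. Control 5 had a contig_3691 log2 level of -3.42, with the next lowest control at -1.17. Control 3 had a contig_807 log2 level of 0.80, with the next lowest control at 2.56.

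The 173 calls between exposed and control arrays outnumber those of most random divisions of the arrays. Of 100 splits of the 16 arrays, the real one included, 2 gave at least as many calls, a share below 0.05. This makes chance unlikely but does not exclude it. The splits were drawn without regard to slide, whereas the real groups each held 4 arrays of each slide. Of the other splits, 96 gave no call, and one with 4 arrays of each slide per group gave 50. The highest other split gave 587 calls and 7 of the 8 arrays in one of its groups came from one slide, a structure of the samples that the slide block (290 calls) and the within-slide counts (95 and 91) take out. Background level of the array, as a linear effect, did not account for the calls. With the negative-control signal added to the slide block, a share of 1 of the 290 calls stayed called in the same direction. That fit called 525 probes. The negative-control signal was nearly balanced between the groups (log2 difference 0.088, exact permutation p = 0.69). Such a covariate could remove few calls, so the test is a weak one. The row of the slide cannot be told apart from exposure, because each row held 1 group. The 34 control probes detected had shifts between rows from -0.65 to 1.12 (log2) with a median of -0.0061. Some of them, eQC-42 at 1.12 included, were compared on slide 2 only. Others varied widely within groups over both slides, up to an SD of 5.99 (log2) for DCP_1_2, and cannot resolve a shift. The median speaks only against a general shift.

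The 30 probes that rose at least 4-fold lay somewhat close together on the array. The median distance from their spots to the nearest spot of another of them was 6.40 positions, against 8.06 in random sets. A share of 0.043 of 1000 random sets lay as close, under the limit of 0.05 set beforehand, so place on the array may play a part. Within 3 positions, 1245 spots of other probes had a median change of -0.079 (log2, quartiles -0.27 and 0.12). That was close to the -0.074 of all other spots, while the set's own spots had 3.21. These values argue against a local rise of signal as the source of the 30 rises. Why the spots lie close was not tested. Whether the 30 contigs are fragments of few transcripts stays open: within groups their levels correlated at a median of 0.72, which is 0.739 of the correlation between duplicate spots of one probe (0.972), between the limits set beforehand; random sets gave 0.06. An effect of cyfluthrin remains a hypothesis, since the slide row is open too.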

How the results depend on the processing

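The floors, the background covariate, the count without the arrays of highest background and the slide block with quantile normalization were chosen after seeing the data. The 173 calls kept their direction in every alternative that tested all 173, and in the filter to probes detected on all arrays, which tested 164. The alternatives reuse the same arrays, so a kept direction is no separate test. Of the 173, 53 stayed called without scaling, 92 with median scaling, 57 within slide 1 and 73 within slide 2. With the slide as a block all 173 did. Counts went outside 1.5 times the main count in several settings. With median scaling 96 probes were called (60 higher, 36 lower). Without scaling the count was 55 (44 higher, 11 lower, against 86 and 87 in the main setting). With the slide as a block it was 290, and within slide 1 and slide 2, which hold fewer arrays, 95 and 91. Array weights gave 296, and an adjusted p below 0.01 gave 99. Slide and background covariates gave 525 (193 higher, 332 lower), and slide block with quantile normalization gave 354. A stricter threshold lowers a count by definition. For the other settings the cause was not tested. Without scaling the median change of all tested probes was 0.11, against -0.07 in the main setting. Leaving out 1 array at a time gave 131 to 209 calls. The difference between within-group and between-group correlations, 0.0074, fell to 0.0046 without the filter on dim probes and no longer passed (one-sided exact permutation p = 0.12); the cause was not tested. The difference between groups in the 75th percentile (log2, exposed minus control) was 0.19 with outlier spots left out and with them kept. Among the 36 alternatives for each named probe, contig_7650, contig_3691 and contig_2561 passed in all and contig_807 missed the threshold in 2, with log2 changes from -3.34 to -1.26 and limma adjusted p up to 0.287.

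Same-numbered control and exposed arrays share a slide and its column, but the numbers were not taken to pair the samples. Same-numbered arrays correlated from -0.38 to 0.72, 3 of 8 pairs above 0.1, and 4 of 16 arrays correlated best with their own number. That range is not one of log2 levels, whose correlations lay between 0.882 and 0.980 for all 120 pairs of arrays. No chance level was computed for these counts, so they do not exclude a pairing. The replicate block gave 167 calls, 137 of them among the 173. The gene list alternatives were not run, as no list had a member; nor were the random slide block (each slide holds both groups) and 1 probe per gene name. Probes near background limit what can be read: 951 were not tested.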

Other observations

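One set of probes swung widely between arrays of the same group. Of the 40 tested probes with the largest SD within groups, 24 formed the largest of 4 clusters, cut at an average correlation of 0.5, with a median SD within groups of 3.05 on the log2 scale against 0.43 over all tested probes, and 0 of the 24 were called. The mean log2 level of the 24 was lowest in exposed 4 (-3.63), control 8 (-3.60), exposed 7 (-3.43) and control 1 (-2.84). It was -0.83 in exposed 2, 1.53 in exposed 8, 1.55 in exposed 3, 1.61 in exposed 5, 1.999 in exposed 6, 2.62 in control 6, 2.74 in control 4, 2.82 in control 3, 3.07 in control 5, 3.81 in control 7, 4.13 in control 2 and 4.22 in exposed 1. The highest array read 232 times the lowest. These 24 probes were picked for their spread and for moving together, so neither is a finding, and the tests of slide, exposure and loss of signal were chosen after it was seen.

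Place on the array is not a likely source of this swing: a share of 0.904 of random sets lay as close together. The slide and its scan protocol cannot be the only source, as the 4 lowest arrays came from 2 slides. The test can say no more, since 4 arrays taken at random would mostly fall on both slides. Exposure is not the whole cause, since both groups hold low and high arrays; the means were 1.59 ± 3.02 in controls and 0.38 ± 2.77 in exposed animals (SD, n = 8 each; exact permutation p = 0.40). Loss of signal on whole arrays stays open by the limits set: without scaling, other probes of like brightness had a median deviation from their own median over arrays of -0.51 in exposed 4, just past the limit of -0.5. It was -0.35 in control 1, -0.06 in control 8 and 0.61 in exposed 7, though all 4 had low levels of the set, and -0.59 in control 4, where the set's level was 2.74. Bright-corner control spots read 1722 in control 1, 1754 in control 8, 2824 in exposed 7 and 2914 in exposed 4 (median, unscaled). They read 6621 in control 2 and 6778 in exposed 1, where the set was highest. Exposed 8 (2537) and exposed 2 (2545) read low too, with the set at 1.53 and -0.83. A technical source that these control spots share with the set was not tested and stays open. The animals' own state, such as sex or moult stage, was not tested, because the labels give none.

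The first principal component followed the negative-control signal over the 16 arrays (Pearson r = -0.80, permutation p = 0.00031; Spearman's rho = -0.84, permutation p = 0.00016; 100000 permutations). On slide 2 r was -0.93 (exact permutation p = 0.0055) and rho -0.86 (exact permutation p = 0.011). On slide 1 r was -0.81 (exact permutation p = 0.028) and rho -0.38 (exact permutation p = 0.36), and without the 2 arrays farthest from the median background r was 0.56 there, so that relation rests on those arrays; over all 16 without 2 it was -0.78. Adjusted over these 3 relations, the p-values of r were 0.00093, 0.0083 and 0.028.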
